A study of Canis lupus familiaris with 6 samples.

How the data were processed

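Total RNA of MDCK-II cells with an inducible scribble hairpin was labelled with Cy3 and hybridised to dog arrays of 45220 spots, 1 array for each of 2 arms at 30, 45 and 60 h, per the labels. The RNA of each array came from 3 wells mixed before labelling, per the labels, so an array is 1 sample and there are no replicate arrays of a condition. The p-values given therefore measure only the spread of a difference over the 3 time points, or of a time effect over the 2 arms, and not the spread between replicate cultures. The labels give each array's arm and time, and these alone set the groups.

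The deposited scanner files hold spot intensity on a linear scale from Agilent Feature Extraction 11.5.1.1 (named both in the submitters' processing notes and in the file headers), protocol GE1_1105_Oct12, build CanFam3.1. Per the file headers, the processed intensity was background-subtracted and spatially detrended by that program, with no normalization between arrays. The deposited series matrix holds the same spots as linear intensity; against the scanner files each array's column equals the processed signal times 1 factor, between 2.30 and 2.62, with no centring of genes, and column medians lie between 150.9 and 171.5. What sets that factor is not given in the sources used here. No other normalization step of the authors is given in the sources used here.

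Of 43803 non-control spots, 64.3% to 68.8% were well above background on an array and 0 were saturated. Spots marked as outliers by the program were left out and the other spots of each of 43603 probes were averaged; 19 probes with no spot left on some array were dropped. Values are log2 of the processed signal minus the array's 75th percentile. Probes were named through their accession, without version, in a RefSeq gene table of assembly UU_Cfam_GSD_1.0, used for names only since its build differs from that of the arrays. In this way 2326 probes received 1 gene symbol, 27 a bare locus number, 0 several and 41250 none. The matches were 2348 of 2441 probes with an NM_ accession and 5 of 5 with an NR_ accession, and 0 of 3746 XM_ and 0 of 19070 Ensembl transcript accessions. Unmatched probes are unnamed here, which says nothing of whether they have a gene. SCRIB and FGF21 each have an entry in the table and 0 matched probes, so their planned values were not analysed here.

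Features entered the tests when well above background on all 3 arrays of at least 1 arm. A gene with several probes was represented by its brightest one, and an unnamed probe counted as a feature of its own, which gave 27581 features, 3.62% of them named. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment). The fit for the arms had time as a 3-level block and arm as the effect, with 2 residual degrees of freedom and an estimated prior of 2.37 degrees of freedom and an SD of 0.107. The slope of the difference added arm by linear time per 15 h, with 1 residual degree of freedom, and time in culture was the contrast of 60 h with 30 h. Counts of 2-fold differences at a single time carry no test and take features well above background on at least 1 of the 2 arrays. A gene not well above background on an array was given only a bound: the bright value against the higher of its own signal and the lowest signal well above background on the dim array, written as at least N-fold.

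The design, the tests, 33 gene lists and the rule for named genes were set before the data were examined. The rule names SCRIB and FGF21; for the arms, up to 13 genes in each direction past the threshold with the same sign at all times, its places filled, as happened for all of them, by genes of at least 0.58 at each time; up to 4 members of each list with the largest mean difference; 6 genes in each direction for the slope, filled by the size of the moderated statistic; and 8 in each direction for time in culture. Some genes that the rule names are not reported here. Lists were tested with limma's camera at a preset correlation of 0.01 against all other features, with an estimated correlation and fry as alternatives; 21 lists had the minimum of 3 tested members, a minimum chosen after the coverage of the lists was seen. A list's median was also placed among 10000 random lists matched in 20 bins of mean signal.

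The alternatives were quantile and median scaling, the deposited series matrix values, no detection filter or detection on all 6 arrays, the mean of a gene's probes, a trended and robust prior, no time term, the slide as a term, leaving out each time in turn, and other thresholds. The planned normexp correction on mean spot signal was run on median spot signal instead (offset 50), a choice made after seeing the data, as were the slide term and left-out arrays for time in culture, unadjusted p for the arms, detection bounds for the 2-fold counts, camera against named features alone and the check of changes within and across slides. Each test was tested on simulated data made from the real features' means and the fitted prior of the spread. The effect was alike at all times for the arms, linear in time for the slope and added at 60 h for time in culture. For the arms, 0%, 52%, 92% and 96% of 50 changed features per size were called at log2 sizes of 0.5, 1, 2 and 3, with 8 false calls among the unchanged of 27581 features. For the slope the shares were 0%, 66%, 96% and 98% with 7 false calls, and for time in culture 0%, 6%, 84% and 90% with 8. A list of 8 genes shifted by -0.4 was called by camera with an adjusted p of 4.09e-10, with 0 other lists called. Genes were drawn independently there and all members shifted alike. The list simulation therefore says nothing of calls where the members of a list are correlated. Effects that vary over the times enter the error of the fit for the arms, which the simulation leaves out. Tables were handled with Python 3.11.15 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9.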

Results

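Gene expression was measured on 6 one-colour Agilent arrays in MDCK-II cells, a dog kidney tubule epithelial line, that carry a short hairpin RNA against scribble under a tetracycline switch. Scribble is a cell polarity scaffold protein. Cells were left without tetracycline or given 5 µg/ml, and total RNA was taken 30, 45 and 60 h later, so that each of the 2 arms has 3 arrays, 1 per time, each of RNA mixed from 3 wells. Between 64.3% and 68.8% of the spots on an array lay well above background, and array profiles correlated at 0.985 to 0.996 with each other. A gene symbol was found for 2326 of 43603 probes, covering 1437 genes. SCRIB, the target of the hairpin, has no named probe here, and neither does FGF21, so the depth of the knockdown and the level of FGF21 were not analysed here. Differences are on the log2 scale, with minus without tetracycline, and the number of arrays limits their precision.

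The comparison of the arms asks which transcripts differ once the hairpin is switched on. The largest differences among named genes were lower levels of the chemokine genes CCL2, CCL8 and CCL20 with tetracycline. The monocyte chemokine CCL2 was 5.52-fold lower at 30 h, 12.4-fold lower at 45 h and 12.2-fold lower at 60 h, a mean difference of -3.23 ± 0.27 (SE, 3 pairs of arrays). Its relative CCL8 was 4.95-, 8.29- and 7.34-fold lower (mean difference -2.74 ± 0.17), and CCL20, which attracts CCR6-bearing lymphocytes and dendritic cells, was 4.05-, 7.01- and 8.04-fold lower (-2.61 ± 0.21). The gelatinase MMP9 was 2.60-, 8.72- and 4.25-fold lower (-2.20 ± 0.35) with both of its probes lower. CXCL10, an interferon-induced chemokine, was 1.71-, 2.23- and 3.78-fold lower (-1.28 ± 0.24). LTB, a membrane ligand of the TNF family, was 1.63-fold lower at 30 h, then at least 1.79-fold lower at 45 h and at least 1.65-fold lower at 60 h, where it was not well above background with tetracycline.

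**Figure D1:**
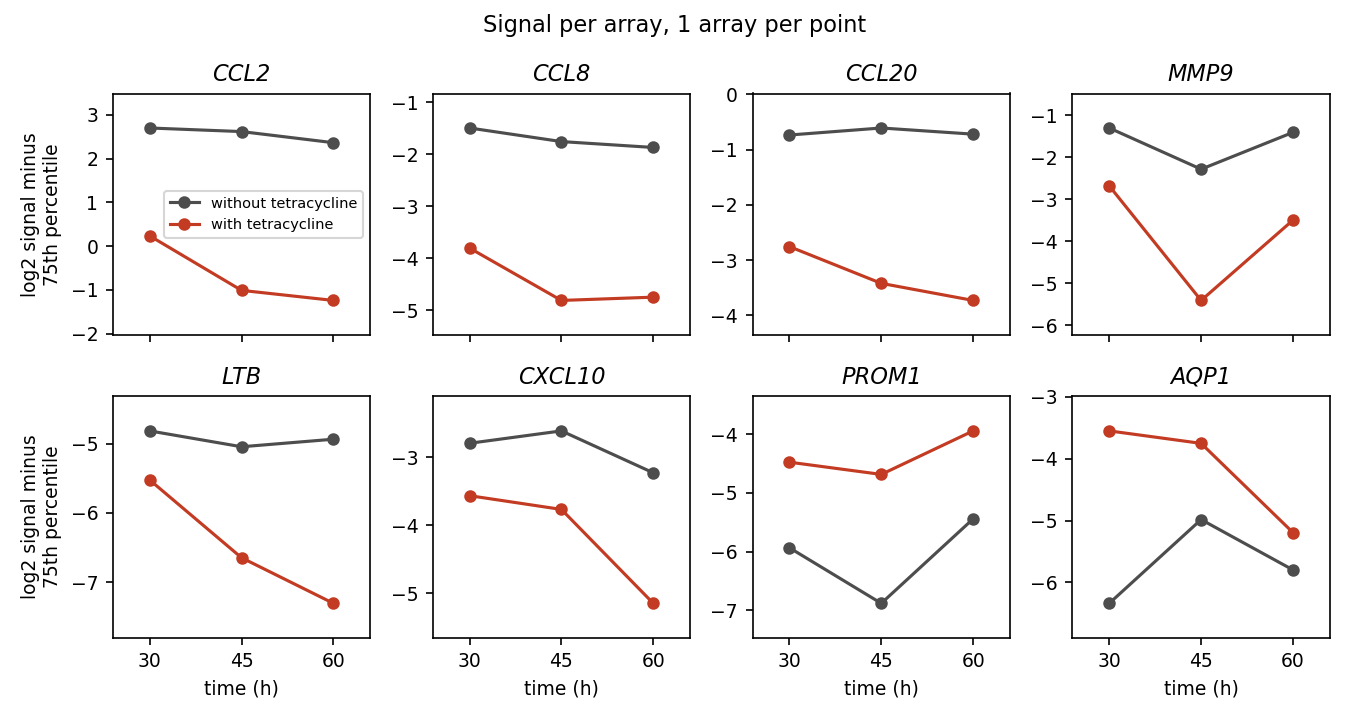
Signal of 8 genes on each of the 6 arrays, as log2 signal minus the array's 75th percentile, against time in hours, without (grey) and with (red) tetracycline. CCL2 lay between 2.36 and 2.70 without tetracycline and between -1.24 and 0.24 with it; LTB with tetracycline, and PROM1 and AQP1 without it, were well above background on only 1 of 3 arrays.

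Other named genes kept the same direction at all 3 times with a measured size of at least 0.58 at each. TAF12, a subunit of the general transcription factor TFIID, had nearly the same difference each time, at 2.17-, 2.13- and 2.20-fold lower (-1.12 ± 0.07). The betaine and GABA transporter SLC6A12 was lower by a mean difference of -0.97 ± 0.08, the sulfotransferase CHST4 by -0.89 ± 0.11, the growth factor BMP4 by -0.85 ± 0.14, and the nucleoside transporter SLC29A1 by -0.79 ± 0.10. GNAS, the stimulatory G protein alpha subunit, was lower on all 5 of its probes (-0.79 ± 0.07). In the other direction stood PROM1, the apical membrane glycoprotein CD133, at least 2.11-fold higher at 30 h, at least 2.64-fold at 45 h and 2.83-fold at 60 h. The water channel AQP1 was at least 4.01-fold higher at 30 h, 2.35-fold at 45 h and at least 1.52-fold at 60 h, and parathyroid hormone, PTH, was at least 1.48-fold, 1.80-fold and at least 1.97-fold higher. PROM1, AQP1 and PTH were each well above background on 1 of the 3 arrays without tetracycline, and the bound of PTH at 30 h, 0.57, lies under 0.58. These 15 genes are 3 of the higher and 12 of the lower ones among 98 features higher and 221 lower in this way.

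None of the 27581 features tested, 998 of them named, passed an adjusted p of 0.05 with limma, the error being the variation of the difference over the 3 times. The smallest adjusted p was 0.109, shared by CCL2, CCL8, CCL20, TAF12, SLC6A12, CHST4, SLC29A1, GNAS, PROM1 and PTH, while BMP4 stood at 0.115, MMP9 at 0.114, CXCL10 at 0.120, LTB at 0.130 and AQP1 at 0.167. At an unadjusted p under 0.05 stood 6422 features (3364 higher, 3058 lower) where chance alone gives 1379, and 228 of these were named (96 higher, 132 lower). The count past the adjusted threshold was 133 with normexp background correction, 16 with limma's trended and robust prior, 17 with no term for time and 1, CCL2, without the 30 h pair of arrays. CCL8, GNAS and TAF12 passed under both normexp and the trended prior. With the slide as a further term the count was 0, and CCL2 stood at -3.03. That term takes up the 45 h pair, which spans both slides, so the fit is the same as leaving that pair out.

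Of 21 gene lists with at least 3 tested members, the interferon-stimulated genes fell as a set with tetracycline (camera, adjusted p = 0.0219). The call did not hold with an estimated correlation (p = 0.0770, adjusted p = 0.960). All 8 measured members had a negative mean difference and 6 were lower at each time, with 2 past the threshold when adjusted over the list alone and 0 over all features. Besides CXCL10 these included the antiviral GTPase MX1, at -0.52, -0.70 and -0.90 for 30, 45 and 60 h, and the immunoproteasome subunits PSMB8 (-0.06, -0.35, -0.73) and PSMB9 (-0.08, -0.37, -0.71). The list's median difference was -0.29, below all but 0.14% of random lists of like signal, and its medians by time were -0.09, -0.32 and -0.45. Random lists were drawn gene by gene, so that share leaves out any correlation among members. The call was also lost with fry (adjusted p = 0.164) and with no term for time (0.0587). It was lost too without the 30 h pair (0.0514) or without the 45 h pair (0.0707). A slide term takes up the 45 h pair, which spans both slides, so for the arms it gives that same fit (0.0707). The list's adjusted p ranged from 0.00436 to 0.960 over the alternatives. For this list and those below, 23.3% of all tested features had an unadjusted p under 0.05 (limma). A member past the threshold adjusted over a short list alone therefore does not by itself show a response particular to that list.

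The NF-kappaB and inflammatory list split: 4 of its 12 members were higher at all 3 times and 3 were lower. CCL2 and CCL20 lay on one side, and on the other the apoptosis inhibitor BIRC3 (0.37, 0.93, 1.16) and, at the later times, the prostaglandin synthase PTGS2 (-0.54, 0.66, 2.55). Its median was 0.13, its mean -0.27 and camera's direction was down (adjusted p = 0.941); adjusted over the list alone, 1 member was higher and 2 lower. The p53 targets measured were 3, and the apoptosis activator BAX (0.26, 0.37, 0.27) and the p53 ligase MDM2 (0.30, 0.30, 0.42) were higher each time, both past the threshold adjusted over the list alone, while PMAIP1 went from -0.18 to 1.05 (list median 0.34, adjusted p = 0.199). The endoplasmic reticulum chaperones HSP90B1 (0.08, 0.20, 0.43) and CANX (0.10, 0.14, 0.21) and the translocon subunit SEC61B (0.18, 0.23, 0.27) were all 3 higher at each time (median 0.23, adjusted p = 0.259). Among 15 apoptosis regulators 5 were higher and 3 lower throughout (median 0.06, adjusted p = 0.941), with BCL2L1, which encodes the survival protein BCL-XL, at a mean difference of -0.31.

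For the epithelial state, 4 of 11 junction genes were lower at all 3 times and 1 was higher (median -0.06, adjusted p = 0.590). The cingulin gene CGN and the keratin KRT19 had mean differences of -0.26 and -0.25, and TJP1 -0.26, with the second of its probes on the other side of 0. CLDN2, a claudin that forms cation channels, stood at 0.06, -0.38 and -1.64. Of 8 mesenchymal transition genes 3 were higher and 3 lower at each time, with a median of 0.07, a mean of -0.16 and camera's direction down (adjusted p = 0.941); 1 was higher and 3 lower when adjusted over the list alone. SNAI2, a transcriptional repressor of E-cadherin, stood at -0.10, 0.99 and 2.60, while vimentin, VIM (-0.15, -0.90, -0.96), S100A4 (-0.35, -0.78, -0.97) and MMP9 were lower. Among 10 tubule transport genes 4 were higher and 5 lower throughout (median -0.16, mean 0.02, camera direction down, adjusted p = 0.590). The drug efflux pump ABCB1 was 8.28-fold higher at 60 h (0.10, 1.18, 3.05), whereas the carbonic anhydrase CA2 (-0.37, -1.06, -1.77) and the potassium channel KCNJ16 (-0.44, -0.90, -1.46) were lower.

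The TGF-beta list, 4 members, likewise went both ways. The collagen gene COL1A1 was higher (0.26, 0.70, 0.82), while the differentiation inhibitor ID3 (-0.24, -0.66, -1.07) and, from 45 h, the cell cycle inhibitor CDKN2B (0.11, -0.43, -1.47) were lower; adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.941). Of 4 lysosomal genes 3 were lower each time (median -0.27, adjusted p = 0.582), led by the cholesterol carrier NPC2 (-0.29, -0.79, -1.08), which alone passed when adjusted over the list alone, and the protease CTSD (-0.06, -0.43, -0.46); NPC1 was the exception at a mean of 0.20. The hypoxia and glycolysis list had 3 of 8 lower and 1 higher throughout (median -0.09, adjusted p = 0.860), with adrenomedullin, ADM, at -0.49 and past the threshold adjusted over the list alone, and the glucose transporter SLC2A1 at -0.03, 0.48 and 1.09. Of 7 actin genes 4 were higher and 1 lower (median 0.06, adjusted p = 0.941), RAC1 standing at 0.31 and the myosin gene MYH9 at 0.21. The 3 cell cycle G2/M genes had a median of -0.08 (adjusted p = 0.941).

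For 9 lists, the TGF-beta list among them, no direction is given, since the median of 8 of them turned under at least 1 alternative setting. Their camera adjusted p was 0.941 each; median, mean and camera's direction differed in sign for the TGF-beta, heat shock, ribosomal protein and basement membrane lists. Among 7 NRF2 targets the haem oxygenase HMOX1 stood at -0.01, 0.81 and 1.71 and the thioredoxin reductase TXNRD1 at 0.02, 0.26 and 1.39, against -0.21, -0.39 and -0.61 for the exporter ABCC2. Among 5 integrated stress response genes VLDLR stood at -0.07, -0.52 and -1.18 and the cystine transporter SLC7A11 at -0.48, 0.73 and 1.94. Of 5 heat shock genes, adjusted over the list alone, 1 was higher and 2 lower, HSPA4 standing at a mean of 0.41, HSPB1 at -0.29 and HSP70 at -0.28. MYC, among 3 immediate early genes, stood at -0.56, -0.35 and 0.68. The 16 ribosomal protein genes had 3 higher and 2 lower throughout, none beyond a mean of -0.14 for RPS3. In 3 oxidative phosphorylation genes COX8A had the largest mean, -0.09, and in 3 basement membrane genes COL7A1, 0.11. Of 5 fibroblast markers COL1A1 was the 1 gene in the same direction at all 3 times.

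Differences between the arms were more numerous at later times. With 1 pair of arrays per time and no replicate check, 1019 features differed by at least 2-fold at 30 h (527 higher, 492 lower), 1498 at 45 h (584 higher, 914 lower) and 2273 at 60 h (904 higher, 1369 lower), of 28799, 30002 and 29790 considered. Where both arrays were well above background the counts were 217 (79 higher, 138 lower), 558 (214, 344) and 1221 (510, 711), so the near-even split at 30 h turned to mostly lower, as it did with dim arrays at their bound (283 higher, 392 lower at 30 h), and with normexp they were 108, 215 and 596. Across tested features the differences correlated at 0.41 between 30 and 45 h, 0.67 between 45 and 60 h and 0.31 between 30 and 60 h, features not being independent replicates. Of 1303 tested features with a 2-fold difference at 60 h, 94.0% had the same sign at 45 h and 74.4% at 30 h. The 30 h and 60 h pairs each lie on 1 slide, and the 45 h pair spans both.

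**Figure D2:**
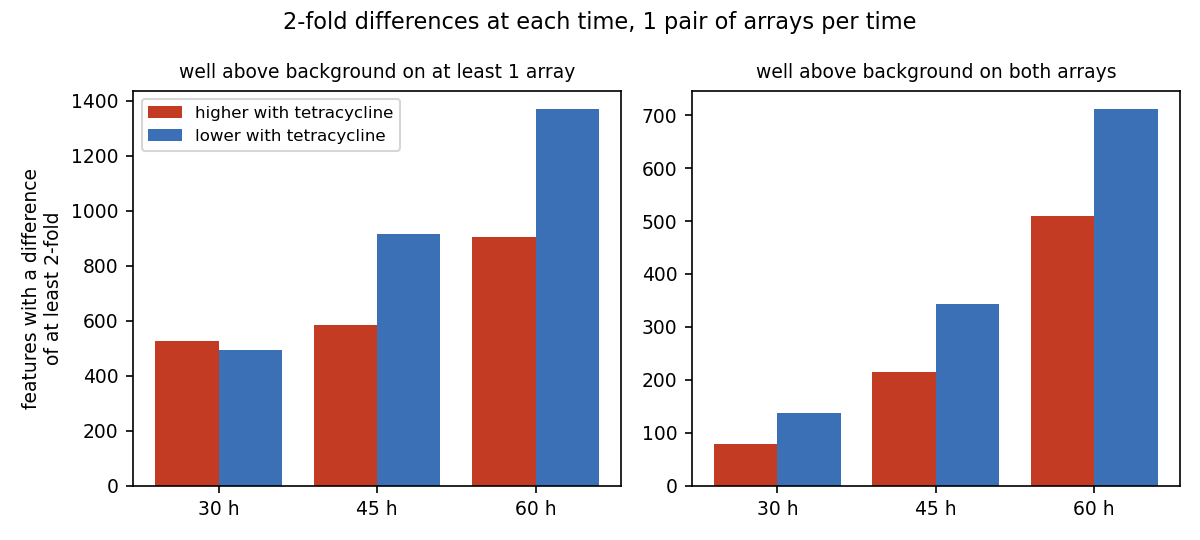
Number of features that differed by at least 2-fold at 30, 45 and 60 h, higher (red) or lower (blue) with tetracycline, in 1 pair of arrays per time. The left panel counts features well above background on at least 1 array of the pair and the right panel those well above background on both; the totals went from 1019 to 2273 and from 217 to 1221.

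Among the 12 genes named for their slope, the difference between the arms moved furthest upward over time for PTGS2 and SNAI2. It moved furthest downward for H19 and FGFR2. These 12 were chosen by the size of the moderated statistic. Other genes had steep slopes too, such as ABCB1 (1.475) and CKMT2 (-1.60). Per 15 h, the difference moved by 1.55 ± 0.12 (SE) for PTGS2 and by 1.35 ± 0.10 for SNAI2. Further upward slopes belonged to the sphingosine phosphate receptor S1PR1 (1.23, at least 3.28-fold higher at 60 h), the desmosomal cadherin DSG3 (1.22), SLC7A11 (1.21) and SNAP91, a clathrin assembly protein with all 3 probes higher (1.12). Downward slopes belonged to the imprinted noncoding RNA H19 (-1.15 ± 0.08), at -0.42, -1.42 and -2.72, to the fibroblast growth factor receptor FGFR2 (-1.05), 5.16-fold lower at 60 h, and to MCPH1 (-0.95), at least 3.01-fold lower at 60 h. FXYD2, a regulatory subunit of the sodium pump, had a slope of -0.88 and the cardiac troponin gene TNNI3 of -0.76. LTB had a measured slope of -0.83, but it was not well above background with tetracycline at 45 and 60 h, and its bounds there, -0.84 and -0.72 against -0.71 at 30 h, leave the slope open. With limma, 0 features passed an adjusted p of 0.05 for this slope (smallest 0.0849), and 5231 had an unadjusted p under 0.05 (2282 upward, 2949 downward); the 12 genes named lay between 0.107 and 0.108. The count was 240 with the arrays scaled by their median, 1607 with normexp, 1781 with the trended and robust prior and 2 among features well above background on all 6 arrays, and of these 12 genes 12, 10 and 11 passed under the first 3. With 1 residual degree of freedom this test rests largely on the shared prior.

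**Figure D3:**
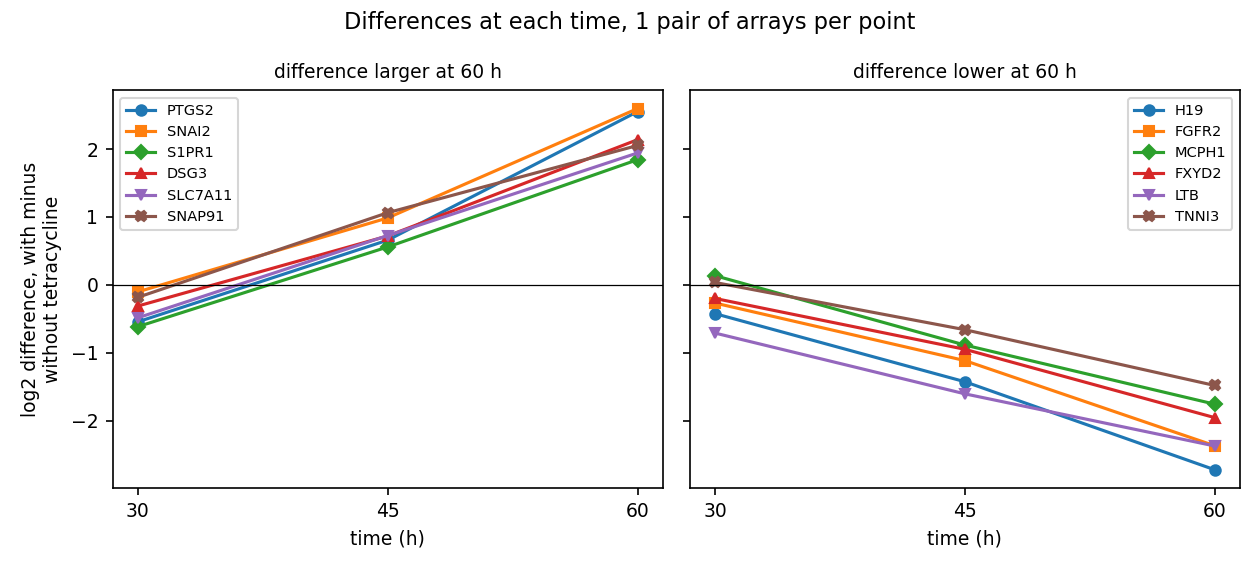
Difference between the arms (log2, with minus without tetracycline) against time in hours for the 12 genes named for their slope, 1 pair of arrays per point. The 6 genes on the left lay between -0.61 and -0.10 at 30 h and between 1.84 and 2.60 at 60 h, and the 6 on the right between -2.72 and -1.48 at 60 h. Points that rest on an array not well above background are LTB at 45 and 60 h and S1PR1 and MCPH1 at 60 h.

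For time in culture, taken over both arms, 2254 features changed from 30 h to 60 h at an adjusted p under 0.05 (limma). Of these 1094 rose and 1160 fell, and 65 were named (29 rose, 36 fell). The 30 h arrays lie on slide 1 and the 60 h arrays on slide 2, so this contrast holds time and slide together. OAZ3, an antizyme that restrains polyamine synthesis, rose most among named genes, by 2.16 ± 0.17 (SE; 2 arrays per time), or 4.48-fold. The phosphodiesterase subunit PDE6B rose by 2.11, the apolipoprotein APOH by 1.96, FHIT by 1.59, the organic cation transporter SLC22A2 by 1.45, ADM by 1.26, the aldolase ALDOC by 1.24 and the pantetheinase VNN1 by 1.16. In the other direction CABYR fell by 1.40, the mitochondrial import chaperone TIMM8A by 1.04, the base excision repair nuclease APEX1 by 0.97 and TCOF1, which acts in ribosomal RNA transcription, by 0.93. RBM12 changed by -0.86, BIVM by -0.78 and the kinetochore gene CENPS by -0.77. Adjusted p for these genes lay between 0.0357 and 0.0378.

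By list, 2 of 8 hypoxia and glycolysis genes rose with time, namely ADM and ALDOC. The small GTPase RHOB rose by 0.63 among the actin genes, NPC1 by 0.64 among the lysosomal ones and the chemokine CCL5, named after its values were seen, by 0.73 among the NF-kappaB ones. The prohibitin gene PHB (-0.76), of mitochondrial quality control, the ubiquitin-conjugating enzyme UBE2S (-0.74), a G2/M gene, the chaperone CANX (-0.53) and the S phase gene TYMS (-0.47) fell. As sets, 0 of 21 lists passed an adjusted p of 0.05 with camera, either for time or for the slope (0 for time with an estimated correlation), and 1 list for time and 3 for the slope had an unadjusted p under 0.05. Both arrays of 30 h lie on slide 1 and both of 60 h on slide 2, so only the 45 h pair, which spans both, parts time from slide. With the slide as a further term the count was 0, as the median SE of the 2254 features went from 0.09 to 0.25 and residual degrees of freedom from 2 to 1. The median size of these features went from 0.71 to 0.67 and OAZ3 from 2.16 to 2.34 ± 0.38. Those features passed partly by their small error, which holds any slide effect, so a check free of that choice took the 1475 features with at least a 2-fold change from 30 h with tetracycline to 60 h without it, across slides: 87.2% had the same sign in the steps within slides on the other 4 arrays, against 69.2% of the remaining features, with a median of 0.55 of the size. The count was also 0 on leaving out any 1 of the 4 arrays of 30 and 60 h and with no detection filter. The direction of the split moved with scaling, from 1094 rising and 1160 falling to 934 and 1818 with median scaling and to 1227 and 827 in the deposited series matrix values.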

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

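The tests of array scaling, of a faulty 60 h array, of cells without the hairpin and of splits at an unadjusted p were chosen only after the results were seen; the tests of second probes, bright features, the CCL2 and CCL8 probes and splits at an adjusted p were chosen before.

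ACKR3, a scavenger receptor for the chemokine CXCL12, was lower with tetracycline at 30 h (-0.85) and 45 h (-0.49) and higher at 60 h (0.72), so that its difference moved by 1.58 from 30 to 60 h. CKMT2, a mitochondrial creatine kinase, went from 2.60 at 30 h to -0.93 and -0.60, a move of -3.21, and the olfactory receptor gene OR6AA6 from 1.35 and 1.35 to -1.15, a move of -2.50. All 3 were picked after their values were seen, because the difference had opposite signs at 30 and 60 h with a size of at least 0.58 on arrays well above background. The slope test over the 3 times did not call them (limma, adjusted p 0.143, 0.271 and 0.231), though ACKR3 passed with normexp (0.00721) and with the trended and robust prior (0.0414), and the opposite signs themselves rest on 1 pair of arrays each. Of 26665 features with such arrays, 974 of them named, 52 met the same condition.

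The first pattern is the larger number of 2-fold differences at 60 h than at 30 h, 2273 against 1019. Probe noise is argued against for named genes with a second probe, which had the same sign in 100% of the 25 that could be checked (95% exact binomial interval from 86.3%). The other features among the 2273, most of them unnamed, were outside this check of second probes. Among 13790 bright features the counts were 24, 130 and 444, a ratio of 18.5, against dim probes as the only source. With 444 bright features against 2273 in all at 60 h, dimmer ones may still hold much of the rise. The ratio of the full counts after quantile normalization was 2.28, against scaling. A fault of 1 array at 60 h that set differences at random would leave signs at 45 h to chance. Yet 94.0% of the 1303 tested features with a 2-fold difference had the same sign there, on other arrays. Of these 1303, 337 were 2-fold the same way at 45 h. A fault that enlarged differences would keep their signs, so the check of signs leaves such a fault open. Features counted among the 2273 but not tested were outside this check. A response to tetracycline that grows with time may account for the pattern, as a hypothesis found and tested on the same data. Whether it would come from the induced hairpin or from tetracycline itself cannot be told. The set holds 0 arrays of cells without the hairpin. The slide, which differs between the 30 h and 60 h pairs, and a difference in growth between the arms were not tested.

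The second pattern is the lower CCL2, CCL8, CCL20, MMP9, LTB and CXCL10 with tetracycline, with a median difference of -2.40. Scaling is argued against, since under other scalings the median kept at least 0.993 of its size. The arrays' 75th percentiles lay between 581 and 639, so scaling had little room to move it. Over all alternatives each gene stayed lower, but sizes varied. The smallest difference was -3.02 for CCL2, -1.90 for CCL20, -1.36 for CCL8, -1.25 for MMP9, -0.60 for CXCL10 and -0.27 for LTB. Whether the CCL8 probe reads RNA of the related CCL2 stays open: the gap between the 2 probes varied with an SD of 0.321 over the arrays, against a median SD of 0.211 between spots of 1 probe, and a spread over single arrays decides nothing here. An effect of tetracycline itself, an antibiotic that could act on inflammatory genes without the hairpin, cannot be told apart from the knockdown, since 0 arrays of cells without the hairpin are part of this set. SCRIB has no named probe here, so its own level does not help.

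The third pattern is the number of features and lists called for the arms. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p the real split gave 0 features and the highest other 0, so all 10 splits gave as many; at an unadjusted p it gave 6422 and the highest other 3987, so 1 split gave as many. That other split parts only the 60 h pair and so is itself a contrast of the arms at 60 h. The split along the slides gave 437, but with time as a block it rests on the 45 h pair alone. It is thus a contrast of the arms at 45 h and does not measure the slide. Among the 4 splits that part all 3 time pairs, the others each having 1 pair turned round, the highest other gave 634. For lists the real split gave 1 and the highest other 1, so 2 splits gave as many.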

How the results depend on the processing

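Normexp on median spot signal, the slide term and left-out arrays for time in culture, unadjusted p and the detection bounds were tests chosen after seeing the data. For the arms, 0 features passed under quantile, median and series matrix scaling, without a detection filter, with detection on all 6 arrays, with mean probes, with the slide as a term and at an adjusted p of 0.1; the count was 133 with normexp, 16 with the trended and robust prior, 17 with no time term, 6422 at an unadjusted p and 0 to 1 on leaving out a time. For the slope the count was 240 with median scaling, 2 with detection on all 6 arrays, 1607 with normexp and 1781 with the trended prior; a slide term leaves it no residual degrees of freedom and was not fitted. For time in culture it was 4121 with normexp, 3775 with the trended prior, 0 with no detection filter, 0 with the slide as a term and 0 to 0 on leaving out an array, where fewer arrays or more terms leave fewer degrees of freedom. Gene lists called numbered 0 with no time term, with the slide as a term, with an estimated correlation and with fry, and 0 to 1 on leaving out a time. The 2-fold counts at 30, 45 and 60 h were 1934, 2602 and 3462 with no filter, 181, 444 and 1112 with detection on all 6 arrays, 217, 558 and 1221 with detection on both arrays and 108, 215 and 596 with normexp; at 3-fold they were 710, 827 and 1098, and with dim arrays at their bound 675, 1024 and 1750. For the arms, the slide as a term and leaving out the 45 h pair are the same fit, counted here under each name. Of 1231 values of named genes under alternatives 1042 stayed on the same side, 49 passed the threshold, 137 lost it, all of these for time in culture, and 3 reversed. Those 3 belong to MYC, at 0.058 with the slide as a term and -0.45 to 0.16 on leaving out a time. The NF-kappaB median was -0.00065 with normexp; the other 11 list medians given with a direction did not reverse. The cause was not tested unless stated. SCRIB and FGF21 under alternatives, and normexp on mean spot signal, were not run. Signal limits the rest: only 64.3% to 68.8% of spots on an array were well above background.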

Other observations

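The test of a slowed change with time was chosen after the results were seen, and the probes given by identifier were picked after their values were seen.

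Lists with fewer than 3 tested members were left without a set test. F3, tissue factor and the 1 measured target of YAP and TEAD, stood at 0.32, 1.1 and 1.56 at 30, 45 and 60 h (mean difference 0.99 ± 0.25, adjusted p = 0.150). CCND1, cyclin D1, the 1 measured gene of the ERK feedback list, stood at 0.09, 0.63 and 1.61 (3.06-fold higher at 60 h, adjusted p = 0.231). FGFR2 was the 1 tested member of the FGF list, and the p38 kinase gene MAPK14 that of the list of ASK1, p38 and JNK kinases, at a mean of 0.15. The mitochondrial protease HTRA2 was higher at each time (0.36, 0.32, 0.29), and in the S phase list the phosphatase CDC25A stood at -0.20, 0.64 and 0.83. The other 9 tested members of these lists, among them PHB and TYMS from the lists of HTRA2 and CDC25A, had mean differences between -0.13 and 0.26. Of the scribble and polarity list 0 of 22 genes had a named probe.

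Several of the largest differences belong to probes with no gene symbol here. A_11_P064056 was at least 4.18-fold lower with tetracycline, being well above background on all 3 arrays without it and 0 with it. A_11_P212238 was at least 2.28-fold and A_11_P000002841 at least 1.67-fold higher, both well above background on 0 arrays without tetracycline and 3 with it. Adjusted p for these 3 probes lay between 0.109 and 0.116.

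One hypothesis was that tetracycline slows the change that cells undergo with time in culture, so that genes rising with time would be lower in the treated arm at 60 h. This was taken to give a clearly negative correlation across features between the 60 h difference and the change from 30 to 45 h, which share no arrays. The correlation was 0.021, features not being independent replicates, but it cannot decide the question. The change was a mean of both arms, so it holds part of the difference at 45 h, which correlated at 0.67 with that at 60 h. Change with time also differed between steps. The step from 30 to 45 h without tetracycline correlated at only 0.21 with that from 45 to 60 h with it.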
